A study of Mus musculus with 8 samples.

How the data were processed

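Chromatin immunoprecipitation with sequencing (ChIP-seq) was done for H3K27ac, histone H3 acetylated at lysine 27, a mark of active promoters and enhancers. Per the labels' protocols, crypts were isolated from the small intestine of male and female mice that had food or were deprived of it for 24 h, and crypts of 4 animals were pooled for each replicate. Trichostatin A, an inhibitor of histone deacetylases, was present in the solutions used to isolate the crypts of both groups, per the labels' protocols. The 8 samples were 2 fed and 2 fasted H3K27ac libraries and the 4 input libraries that go with them. Processed files of the 4 H3K27ac libraries were used; values of the inputs alone were not analysed here. Libraries are named below by the replicate numbers in their labels, as fed 1, fed 4, fasted 2 and fasted 5. The replicates were separate pools of animals.

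Each deposited file held the authors' peaks of a single library, so peaks were not called on pooled replicates, and held the chromosome, start, end, name and a score of each peak. Per the submitters' processing notes, FastQC, Bowtie 1.1.2, SAMtools 1.9 and deepTools 1.5.11 were used with the mouse build mm9; their settings are not given in the sources used here. The names of the peaks and of the deposited files point to MACS, run without a shifting model and on a pair of tracks whose roles the names do not state; its version is not given in the sources used here. The score of each peak is the authors' own value. Its scale is not stated; the lowest score was 50.01 in fed 1 and 50.0 in the other libraries, and 1282 peaks of fasted 5 shared a score of exactly 3100, so these cannot be ranked against each other; 142 peaks of fasted 5 scored higher. A score depends on the depth and the enrichment of its library, so scores were used to rank or filter peaks within a list. The score minimums tried as alternatives apply a single value to all lists and remove far more of the fed peaks; at 200 they leave 640 peaks of fed 4 and 20009 of fasted 5. The files hold no read counts, so the depth of each library is unknown and no interval that needs depth is given.

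The peak positions were used as deposited. The gene table at hand is for build GRCm38, and on chromosome 11 only 13.5% of its 3214 distinct ends of protein-coding genes lay under a fasted 2 peak when unshifted, about the median of 13.2% over all shifts of up to 200 kb, against 23.2% at a shift of -186.5 kb. Positions were not converted between builds and no gene names were assigned. The gene comparisons, the promoter shares and the 25 gene lists fixed beforehand were therefore not run. Coordinates below are mm9 and count from 1.

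Peaks of the 4 libraries were merged into regions wherever they overlapped by 1 bp or more. A region with a peak in both fasted and neither fed library is called fasted-only, and the reverse fed-only. Overlap between libraries was measured as the Jaccard index, the bases covered in both lists divided by those covered in either. Its chance level was taken from 20 random circular shifts of the first list of each pair along its chromosomes, with the other list left in place. Domains were made by joining peaks of a library across gaps of up to 12500 bp. Score percentiles are the share of peaks of the same list with that score or a lower one, so the tied peaks of fasted 5, which span percentiles 96.0 to 99.6, stand at 99.6; with the lower edge in its place, an alternative chosen after seeing the data, the fixed rule names the same 10 fasted-only regions. Values per library were compared by a two-sided exact permutation test, and the overlap by an exact test over the 3 splits of the 4 libraries into pairs; with 2 libraries in each group neither can go below p = 0.333. No test was made for single regions for the same reason. Chromosomes were compared by two-sided Fisher's exact tests over regions, with Benjamini-Hochberg adjustment over the 20 chromosomes; regions are not replicates, so these p-values describe these lists. Intervals of shares are exact 95% binomial (Clopper-Pearson) intervals and cover counting error only. Named regions follow a fixed rule: the 10 fasted-only and 10 fed-only regions with the highest value of the lower of their 2 within-library score percentiles, and the 5 widest regions with a peak in all 4 libraries. A fasted-only region that this rule names is not reported here.

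The rule for named regions, the tests and most alternatives were fixed before the data were examined; these alternatives were score minimums of 100 and 200, equal numbers of top-scoring peaks (15504 from each library), other definitions of overlap and region, and leaving out each library in turn. The comparison at equal covered length (21.9 Mb of top-scoring peaks from each library), the comparisons between chromosomes, the overlaps by autosome, the widths of shared regions and the fed peaks by fasted score were chosen after seeing the data. The deposited file names carry the number 10 (fed 1 and fasted 2) or 11 (fed 4 and fasted 5), and values within each number are given. No pair of libraries had a peak with identical start and end, so no list was a copy of another. The region code was tested on simulated lists made from 6640 real regions, in which it recovered 200 of 200 planted fasted-only and 200 of 200 planted fed-only regions. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; the overlap code was checked against bedtools 2.31.1.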

Results

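H3K27ac was profiled in small intestinal crypts, the pits of the intestinal lining that hold its stem cells, from mice with food and from mice deprived of food for 24 h. The fed and the fasted group had 2 libraries each, and each library came from a pool of 4 animals. The deposited peak lists held 27640 peaks in fed 1, 15504 in fed 4, 37974 in fasted 2 and 35917 in fasted 5. Sequencing depth is unknown, and it sets how many peaks can be called.

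The first comparison asked how much of the crypt genome carried H3K27ac peaks in each feeding state. The fasted lists were longer and covered more of the genome, with 36945.5 ± 1454.5 peaks against 21572.0 ± 8581.4 in the fed lists (mean ± SD, n = 2), 1.71 times as many. Fasted peaks covered 104.2 ± 7.0 Mb and fed peaks 35.3 ± 19.0 Mb (SD, n = 2), a ratio of 2.95. The median peak was 1893 ± 260.2 bp wide in the fasted and 1277 ± 124.5 bp wide in the fed libraries (SD, n = 2). Both fasted libraries lay above both fed libraries in peak number, covered length and median width. Each of these differences gave p = 0.333 in the two-sided exact permutation test, the smallest that 2 against 2 libraries allow. The fed libraries also differed from each other, and without fed 4 the difference in peak number was 9305.5 rather than 15373.5. Among peaks with a score of 200 or more, of which fed 4 had 640 and fasted 5 had 20009, the median width no longer separated the groups (difference 160.8 bp, exact permutation p = 0.667).

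**Figure D1:**
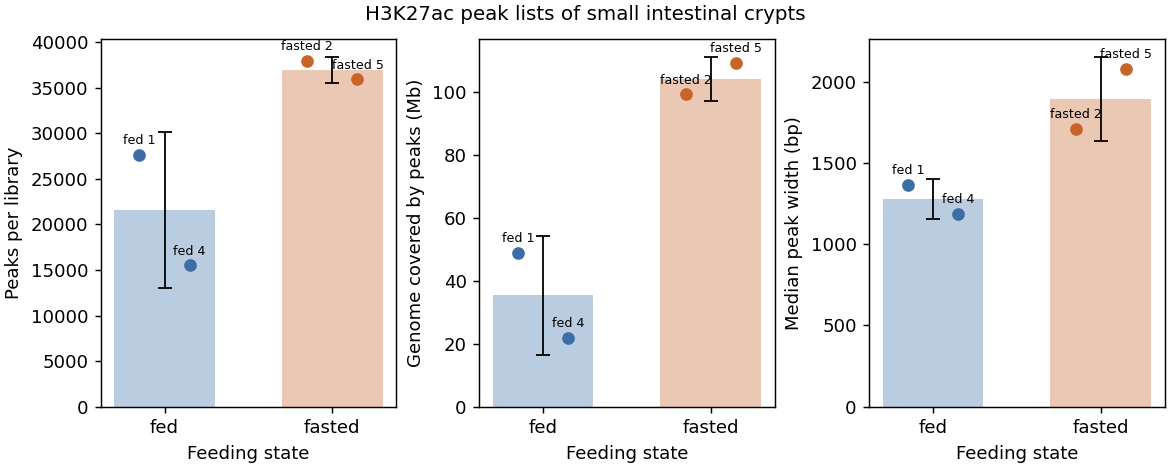
Peaks per library, genome covered by peaks in Mb, and median peak width in bp for the fed (blue) and fasted (orange) H3K27ac libraries; points are libraries, bars are means and error bars are SD (n = 2). Both fasted libraries lie above both fed libraries in each panel, with 35917 or more peaks against 27640 or fewer.

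The second comparison asked whether libraries of the same feeding state shared more of their peaks. The 2 fasted libraries overlapped most of all pairs, with a Jaccard index of 0.65. The 2 fed libraries had an index of 0.254, below that of fed 1 with fasted 2 (0.396) and of fed 1 with fasted 5 (0.368), and above that of fed 4 with fasted 2 (0.188) and with fasted 5 (0.173). All pairs lay far above their chance level, which reached at most 0.027 for any random shift. The mean index within feeding states was 0.452 and that between them 0.281, a difference of 0.171 (exact permutation over 3 splits, p = 0.333). This difference rested on the fasted pair, since it was -0.016 without fasted 2 and -0.038 without fasted 5. It was 0.469 without fed 1 and 0.268 without fed 4. It turned to -0.148 when overlap was the share of peaks of the shorter list that touched the other list by 1 bp or more. That share can rise with the length of the other list. The other list was a fasted one in each pair between feeding states, but fed 1 (48.8 Mb) in the fed pair (69.2%). Part of the -0.148 may therefore reflect list length, though the fasted pair also had only 74.1%. With reciprocal overlap of 50% or more the within-minus-between difference was 0.243. The fed pair then shared more (32.6% of the shorter list) than fed 1 did with fasted 2 (30.0%) or fasted 5 (22.5%). Unlike peak widths, as between fed and fasted lists, hold reciprocal overlap down. Both fed libraries overlapped less with fasted 5 than with fasted 2 on 19 of 19 autosomes, which are not replicates. Fed 1 shares its file number with fasted 2, but fed 4 shares its number with fasted 5. Fasted 5 covered more (109.1 against 99.2 Mb), which can lower its index. At equal covered length the order stayed, with 0.303 for fed 1 with fasted 2 and 0.279 with fasted 5. For fed 4 the values were 0.215 and 0.203, so covered length alone does not account for the order. In the lists as deposited, the share of the shorter list touching by 1 bp or more was nearly equal. It was 85.5% with fasted 2 and 85.1% with fasted 5 for fed 1, and 87.7% and 87.3% for fed 4. With 15504 top-scoring peaks from each library the fed pair still had a lower index (0.272) than fed 1 with fasted 2 (0.391) or fasted 5 (0.357). At equal covered length the within-minus-between difference was 0.088. The index was then 0.412 in the fasted pair, 0.263 in the fed pair and 0.203 to 0.303 between feeding states. The index cannot exceed the ratio of the shorter to the longer covered length. Lists of unlike length, such as fed 4 (21.9 Mb) and fasted 2 (99.2 Mb), therefore hold it down, so part of the 0.171 may reflect list length.

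The third comparison asked at which regions the feeding states differed. Merging all peaks gave 43091 regions, of which 6931 had a peak in all 4 libraries. A further 8319 regions, 19.3% of the total, were fasted-only and 128, 0.3%, were fed-only. Pairing a fed with a fasted library in place of the feeding states gave more even counts. A peak only in fed 1 and fasted 2 was found at 825 regions, against 197 only in fed 4 and fasted 5. Only fed 1 and fasted 5 had a peak at 597 regions, against 316 for only fed 4 and fasted 2. Each such pair joins a shorter fed list and a longer fasted list. This contrast therefore cannot separate feeding state from list length. Within the file number 10, 20472 regions had a fasted 2 peak without a fed 1 peak and 4017 the reverse. Within the number 11, 26678 had a fasted 5 peak without a fed 4 peak and 1971 the reverse. Nearly all fed peaks lay at regions that also had fasted peaks: 90.3% of fed 1 peaks and 91.8% of fed 4 peaks overlapped a peak of either fasted library. In the other direction, 51.8% of fasted 2 and 48.9% of fasted 5 peaks overlapped a fed peak.

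The counts of fasted-only and fed-only regions depended on how the lists were made equal. With the same number of top-scoring peaks from each library, 2830 regions were fasted-only and 285 fed-only. With top-scoring peaks of the same covered length, which keeps 15504 narrow peaks of fed 4 but 2616 wide peaks of fasted 5, the order turned, with 82 fasted-only and 1644 fed-only regions.

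**Figure D2:**
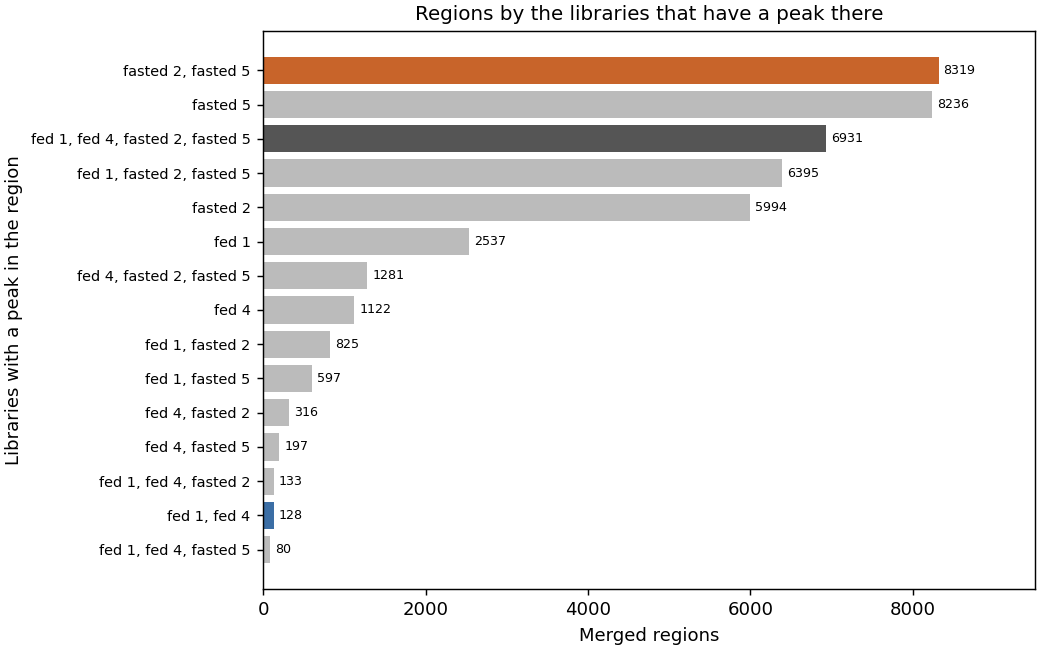
Number of merged regions (horizontal axis) by the libraries that have a peak there (vertical axis); orange marks fasted-only, blue fed-only and dark grey regions found in all 4 libraries. The fasted-only bar holds 8319 regions and the fed-only bar 128.

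Fasted-only regions were narrower and scored lower than regions found in all 4 libraries. Their median width was 2248 bp against 6530 bp, and their median score percentile was 43.7 in fasted 2 and 49.7 in fasted 5, against 87.7 and 86.3 for regions in all 4 libraries. A merged region spans the peaks of every library that has one there, so regions found in all 4 libraries are wider in part by construction. Fasted-only regions lay a median of 9580 bp from the nearest fed peak, and 26.1% were within 10000 bp of a region found in all 4 libraries. The 128 fed-only regions lay a median of 885 bp from the nearest fasted peak. The fasted lists hold more peaks and cover more of the genome, which by itself shortens this distance. Of the fed-only regions, 52.3% were within 10000 bp of a region found in all 4 libraries. Their median score percentiles were 31.2 in fed 1 and 34.1 in fed 4.

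Whether a region found in both fasted libraries also had a fed peak followed its rank in the fasted lists. Of the 1559 regions below the 10th fasted score percentile, 19.4% had a fed 1 peak and 8.9% a fed 4 peak. Of the 2447 regions at or above the 90th percentile, 98.5% had a fed 1 peak and 85.5% a fed 4 peak, and 21 regions, 0.9% (exact 95% interval 0.5 to 1.3%), had neither.

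**Figure D3:**
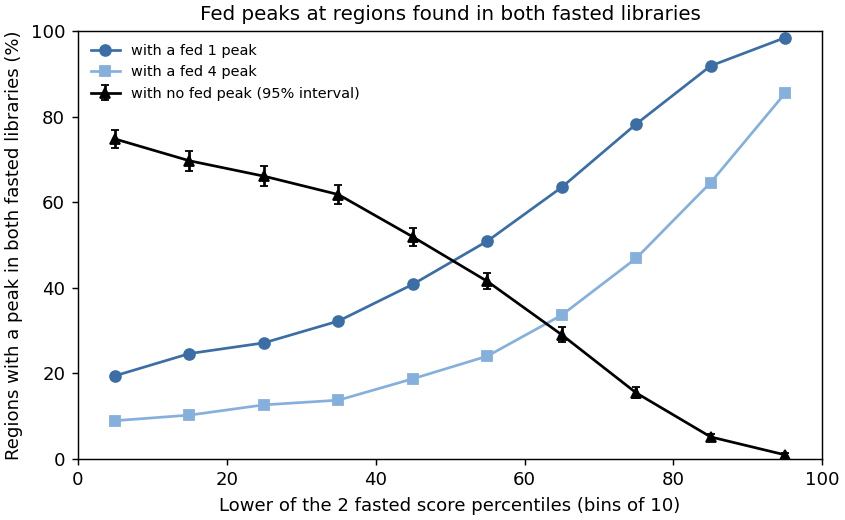
Share of regions found in both fasted libraries that have a fed 1 peak, a fed 4 peak or no fed peak (vertical axis, %), by the lower of the region's 2 fasted score percentiles (horizontal axis, bins of 10); error bars are exact 95% binomial intervals. The share without a fed peak falls from 74.8% in the lowest bin to 0.9% in the highest.

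Among the strongest fasted-only regions was a region on chromosome 6 (5456174 to 5464017, 7844 bp), at score percentile 98.3 in fasted 2 and at the tied score of 3100 in fasted 5, with the nearest fed peak 38439 bp away. Another was on chromosome 11 (60228363 to 60234639), at percentile 97.7 in fasted 2 and at the same tied score in fasted 5. The region on chromosome 15 (38225351 to 38233562) was 8212 bp wide and lay 5304 bp from a fed peak. The others lay on chromosome 1 (58447630 to 58451695, and 13361203 to 13365364), chromosome 11 (95168546 to 95173674), chromosome 6 (24611375 to 24616231), chromosome 4 (40915227 to 40919415) and chromosome 3 (122685221 to 122689944). These 6 were 4066 to 5129 bp wide, and the lower of their fasted percentiles ranged from 91.8 to 93.6. No gene was assigned to any of them.

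The fed-only regions named by the rule stood lower within their own lists. The strongest lay on chromosome 13 (114191418 to 114193065, 1648 bp), at score percentiles 80.2 in fed 1 and 90.7 in fed 4, with a fasted peak 1019 bp away. The next, on chromosome 1 (134240741 to 134243907, 3167 bp), reached percentiles 75.8 and 87.0 and began or ended 77 bp from a fasted peak. A pair lay close together on chromosome 2 (133285078 to 133287763, and 133319055 to 133320856), at lower percentiles of 63.8 and 61.5, with fasted peaks 9896 and 197 bp away. The region on chromosome 14 (77174161 to 77175898) lay 3311 bp from a fasted peak. The other named regions lay on chromosome 15 (101975006 to 101976976), chromosome 11 (120766810 to 120768843), chromosome 6 (135287871 to 135289421, and 108500940 to 108502100) and chromosome 2 (121271107 to 121272815), each within 667 bp of a fasted peak.

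At regions found in all 4 libraries, fasted peaks covered more bases. The median length covered per region was 5809 bp in fasted 2 and 5898 bp in fasted 5, against 3359 bp in fed 1 and 1764 bp in fed 4, giving 5853.5 ± 62.9 bp and 2561.5 ± 1127.8 bp (mean ± SD, n = 2). Both fasted libraries covered more than both fed libraries at 6327 of 6931 regions (91.3%), and both fed libraries more than both fasted at 12 (0.2%); chance orderings of 4 libraries would give 16.7% each way, but a difference in covered length across whole lists orders most regions alike. Fed peaks were also more fragmented. The mean number of peaks per region was 2.17 in fed 1 and 1.74 in fed 4, against 1.63 in fasted 2 and 1.35 in fasted 5. A region spans the peaks of all 4 libraries, so lists of narrower peaks can hold more peaks per region by construction. Scores across these regions ranked most alike in the fasted pair (Spearman rho 0.72) and less so in the fed pair (0.39), while fed 1 had rho 0.55 with fasted 2 and 0.5 with fasted 5, and fed 4 had 0.36 and 0.33. These correlations are across regions, which are not independent replicates.

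The same loci held the largest clusters of peaks in both feeding states. Domains, made by joining neighbouring peaks, numbered 4850 with 2 or more peaks in fed 1, 3041 in fed 4, 6484 in fasted 2 and 6775 in fasted 5 (fasted against fed, exact permutation p = 0.333, n = 2). By bases covered, the largest domain of every library lay at the same locus of chromosome 8. It spanned 129096924 to 129447355 in fed 1, where peaks covered 235.4 kb, and 129159356 to 129446369 in fed 4, where they covered 149.5 kb. In fasted 2 it spanned 129178832 to 129453280 with 254.0 kb covered, and in fasted 5 it spanned 129178125 to 129452721 with 231.4 kb covered. These spans differ in length. Over the span of the fed 1 domain, peaks covered 171.0 kb in fed 4, 299.9 kb in fasted 2 and 273.1 kb in fasted 5. The second-ranked domain lay at a single locus of chromosome 15 in all 4 libraries, with 118.6 kb covered in fed 1, 70.7 kb in fed 4, 159.2 kb in fasted 2 and 142.0 kb in fasted 5. The third-ranked lay on chromosome 6 in fed 1 and fed 4 (108368818 to 108501922 in fed 1), at another locus of chromosome 6 in fasted 2 (86420999 to 86660589) and on chromosome 1 in fasted 5 (135014693 to 135210549). Covered lengths depended on the gap joined. With gaps of up to 5000 bp the largest was 118.8 kb in fed 1, 47.6 kb in fed 4, 254.0 kb in fasted 2 and 158.4 kb in fasted 5. The loci were not compared at that gap.

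The widest region with a peak in all 4 libraries was part of the chromosome 8 locus (129250113 to 129305695, 55583 bp), with 47564 bp covered in fed 1, 31832 bp in fed 4, 55308 bp in fasted 2 and 54220 bp in fasted 5. The others were on chromosome 2 (143982010 to 144037305), chromosome 4 (45484148 to 45537697), chromosome 8 (124797508 to 124850951) and chromosome 7 (139938074 to 139988776). At the first 3 of these, each fasted library covered 50195 bp or more and each fed library 45306 bp or less. The chromosome 7 region differed between the fasted libraries: peaks covered 50352 bp in fasted 5 and 3551 bp in fasted 2, beside 42602 bp in fed 1 and 25149 bp in fed 4.

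Fasted-only regions were not spread over the chromosomes as the regions of all 4 libraries were. Chromosome X held 207 of the 8319 fasted-only regions (2.49%) and 2 of the 6931 regions found in all 4 libraries (0.03%), with an adjusted p of 1.1e-50 in Fisher's exact test. Chromosome 13 held 4.6% of fasted-only against 3.49% of shared regions (adjusted p = 0.0038, Fisher's exact test). Chromosome 11 held 6.97% against 9.84% (adjusted p = 2e-09) and chromosome 19 held 3.29% against 4.13% (adjusted p = 0.036, both Fisher's exact test). The other 16 chromosomes did not pass the 0.05 threshold. In the single lists, chromosome X held 25 of 27640 peaks in fed 1 (0.09%, exact 95% interval 0.059 to 0.133%), 6 of 15504 in fed 4 (0.039%, 0.014 to 0.084%), 293 of 37974 in fasted 2 (0.772%, 0.686 to 0.865%) and 564 of 35917 in fasted 5 (1.57%, 1.444 to 1.704%). In the lists as deposited the feeding states did not overlap in this share (exact permutation p = 0.333, n = 2), and the fasted libraries differed from each other beyond counting error. The difference between the group means was 1.106 percentage points, and 0.707 without fasted 5. With the same number of top-scoring peaks from each library it was 0.838 and the feeding states did not overlap. The shares were then 0.032% in fed 1, 0.039% in fed 4, 0.4% in fasted 2 and 1.348% in fasted 5. At equal covered length it was 0.057 and the feeding states overlapped, with 0 of 6895 peaks on chromosome X in fed 1, 6 of 15504 in fed 4, 0 of 2835 in fasted 2 and 4 of 2616 in fasted 5. That setting keeps only the strongest fasted peaks. In the deposited lists, X peaks stood at mean score percentiles of 39.9 in fasted 2 and 46.0 in fasted 5. Chromosome Y held 4 peaks in fasted 5 and 0 in the other 3 lists.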

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

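The equal covered length and the chromosome X alternatives were chosen after the data were seen. Of 63 alternatives run, 39 kept the direction of a difference or stayed within 1.5 times a count, 21 moved a count by more than that or a correlation beyond its 95% interval, and 3 reversed a difference. The higher peak number and covered length in the fasted libraries kept their direction under the alternatives run for each, and so did the median width, though it shrank to 160.8 bp at a score of 200 or more. The mean share of X peaks kept its direction too, with a difference of 0.838 points at equal peak number. At equal covered length the difference of 0.057 points rested on 4 peaks of fasted 5, and fasted 2 (0%) lay below fed 4 (0.039%). The p of these differences was never below 0.333, so no alternative could end a call. The within-minus-between Jaccard difference of 0.171 reversed to -0.148 as the share of peaks of the smaller list overlapping by 1 bp or more. It was 0.243 with reciprocal overlap of 50% or more and 0.088 at equal covered length. It was -0.016 without fasted 2, -0.038 without fasted 5, 0.268 without fed 4 and 0.469 without fed 1. The cause of these changes was not tested, though list length may account for part of the -0.148. Fasted-only regions (8319 as deposited) numbered 2830 at equal peak number, 82 at equal covered length, 13194 when a library had to cover at least 50% of a region, 20472 and 26678 within the file numbers 10 and 11, and 9636 (without fed 4), 14911 (fed 1), 18310 (fasted 5) and 18336 (fasted 2) with a library left out. Fed-only regions (128 as deposited) numbered 9 and 0 at score minimums of 100 and 200, which by construction remove more of the fed peaks, 285 at equal peak number, 1644 at equal covered length, 73 with peaks within 1000 bp merged, 4017 and 1971 within the numbers 10 and 11, and 291 (without fasted 2), 312 (fasted 5), 1274 (fed 1) and 2681 (fed 4) with a library left out. Leaving out a library or comparing single pairs asks for a peak, or for the absence of a peak, in fewer libraries. By construction this lets more regions in. With the mean in place of the highest score in a region, Spearman's rho fell to 0.26 in the fed and 0.63 in the fasted pair; the cause was not tested. The alternatives for genes, gene lists and promoter shares were not run, since no genes were assigned. No paired analysis was possible because the labels give the fed (1 and 4) and fasted (2 and 5) libraries no replicate number in common; the file numbers are not stated to mark pairs, and the region counts within them, which come from no test, had more fasted-only than fed-only regions in both. Unknown depth limits every count of regions: a region without a peak is not shown to lack H3K27ac.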

Other observations

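The tests of list length, sensitivity, sex makeup and the strata of score and width were chosen after the results they bear on had been seen; the score-matched comparison of chromosome X was set before its result was seen, though after the low number of X peaks was.

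Beyond the regions that the fixed rule names, 11 more regions lay at or above the 90th fasted score percentile in both fasted libraries with no fed peak. They were chosen after their values were seen. They lay on chromosome 1 (43989400 to 43993172), chromosome 5 (114591789 to 114598237), chromosome 6 (5513496 to 5520686), chromosome 7 (17366382 to 17371474), chromosome 8 (124170417 to 124178485), chromosome 10 (93102848 to 93106294), chromosome 11 (87797706 to 87802033), chromosome 17 (30550245 to 30558084), chromosome 18 (53404280 to 53412149, and 64672489 to 64677827) and chromosome 19 (34950946 to 34957411). The region at 5513496 lies close to the named fasted-only region that ends at 5464017 on chromosome 6.

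These 21 strong fasted regions without a fed peak were narrower (median 5339 bp) than the other strong regions (8514 bp), and fed 1 missed 36 and fed 4 missed 354 of the 2447 strong regions. If each fed list missed regions independently within strata of score percentile and width, 9.3 ± 3.0 (binomial SD) would lack both, fewer than the 21 seen. With the lower edge of tied scores the expected number was 9.4 ± 3.0. Fed peaks can themselves widen a merged region, so width depends in part on the outcome. These strata therefore cannot settle whether narrow width and lower score explain the excess. A property of these regions that lowers both fed lists, and an acetylation difference between fed and fasted crypts, stay open. The second is a hypothesis that read counts over these 21 regions could test in other libraries. Those of the present libraries could not, since the regions were chosen from their lists. The strata were few, so differences in score or width within a stratum may account for part of the excess.

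The 8319 fasted-only against 128 fed-only regions were weighed against technical explanations. Lower sensitivity of the fed lists, so that peaks are missed in both, stays open: the share of both-fasted regions without a fed peak fell in each bin of rising fasted score, from 74.8% to 0.9%, as it would too if fasting added mostly weaker sites. Regions missed by both fed lists outnumbered those that independent misses would give in every bin, with 1166 against 1144.9 in the lowest and 462 against 346.7 between percentiles 70 and 80, and scores that differ within a bin would also raise this number. Longer fasted lists cannot be told apart from a difference between the groups, because the ratio of fasted-only to fed-only regions was 9.93 at equal peak number and 0.05 at equal covered length. A gain of H3K27ac on fasting is a biological explanation that stays open and untested, since both fasted lists exceed both fed lists and depth is unknown.

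The few chromosome X peaks in the fed libraries were weighed against low sensitivity of the fed lists for regions of that score, and the test argued against it. Of 230 X regions with a peak in both fasted libraries, 21 had a fed 1 peak, where autosomal regions of the same fasted score gave an expected 99.7 ± 7.0 (binomial SD). In fed 4 there were 4 against 50.2 ± 5.9. The regions were matched on fasted score alone. In the lists as deposited, the share of X peaks also rose with the median score of the list. Median scores were 74.1 in fed 4, 87.7 in fed 1, 134.5 in fasted 2 and 263.7 in fasted 5. Lower sensitivity is therefore not excluded as part of the reason. A different share of male animals in the pools stays open, since the labels give no sex per pool. Whether the sex of the animals changes the share of X peaks was not tested. The 2 fasted pools, of the same feeding state, already differed by 0.799 percentage points in the share of X peaks, beside 1.106 between the feeding states; the 4 chromosome Y peaks, all in fasted 5, go against fewer males in that pool as the reason for its high X share, but are too few to decide. Sex makeup and feeding state cannot be told apart here, and an effect of feeding on chromosome X stays open and untested.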
